A study of Homo sapiens with 8 samples.

How the data were processed

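RNA from 2 human cancer cell lines was measured on Illumina HumanHT-12-type BeadChips, 8 arrays in all. KHOS is an osteosarcoma line and T98G a glioblastoma line. Per the labels, cells of each line were infected with a viral vector that carried either the green fluorescent protein GFP, the control, or the microRNA miR-190, and each of the 4 groups has 2 arrays. Total RNA was isolated with TRIzol and biotinylated cRNA was made with the Ambion MessageAmp kit. The 4 KHOS arrays lie on a chip of their own and so do the 4 T98G arrays. Chip and cell line therefore cannot be told apart, while a comparison of vectors within a line stays on the same chip. On each chip the 2 arrays of a vector lie side by side, so vector and position on the chip cannot be told apart either.

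The deposited non-normalized table holds an intensity per probe and array, the mean bead signal on a linear scale with no background subtracted and no normalization. Per the file headers it also holds a detection p value (p_value) per probe and array, set against the negative controls of that array. The deposited table of processed values holds log2 intensities. Their quantiles were shared by the 4 arrays of a line and not by both lines, which places the quantile normalization within each line. The submitters' notes name limma with no version and no role. Each processed column ranked the probes of its own array with a Spearman correlation of 1, against at most 0.888 with any other array, so the columns of both tables were matched.

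The main values came from the non-normalized table. Background was corrected with limma's normexp method on negative controls inferred from the detection p values, with an offset of 16, followed by quantile normalization over all 8 arrays and log2 transformation. A probe was called above background on an array at a detection p under 0.01, and probes above background on at least 2 of the 8 arrays were tested, which left 18030 of 47318. Of the tested probes 14394 carried 1 gene symbol, and these stood for 10889 genes. Gene names came from the platform table, and 30072 of 30111 probes with 1 symbol matched the current gene table of the assembly GRCh38.p14 by gene ID. That table served for names and for the order of neighbouring genes only, since the series names no genome build.

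A linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual and 2.68 prior degrees of freedom). The contrasts were miR-190 minus GFP in each line and the difference between those effects, T98G minus KHOS. The common effect was fitted with line and vector as additive terms. The Benjamini-Hochberg adjustment ran over all tested probes of a contrast, the tests were two-sided, and a probe was called at an adjusted p under 0.05. For 29 gene lists and 6 lists of cell type markers, camera with a preset correlation of 0.01 compared each list with the other genes, on the probe per gene with the highest mean. The adjustment ran over the 31 lists with at least 5 tested genes. Camera with an estimated correlation and fry were run beside it. The lists, contrasts, thresholds, alternatives and the rule for naming genes were chosen before the data were examined.

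The rule for named genes took, per line, up to 12 rising and 12 falling genes with the largest absolute change among called probes with 1 symbol whose miR-190 arrays both lay on the same side of both GFP arrays. Loci without an approved-style name were left out. Where no probe passed, it took the 6 rising and 6 falling genes with the smallest unadjusted p. It added up to 5 interaction calls per direction, up to 4 members of each list with the smallest p in either line, the gene TLN2 that holds the MIR190A locus, the MIR190A and MIR190B probes and 7 reported targets of miR-190. Other genes named here were members of those lists or were chosen after their values were seen, as stated beside them.

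A probe that no array of a group showed above background has no fold change, only a bound. The bound was taken against the lowest normalized value of any probe above background, averaged over the 2 arrays of that group, and is written as at least so many fold. For a named gene above background on 1 of the 2 arrays of a group, the other array was set to that lowest value if it lay below it, a bound added after the results were seen.

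To see whether neighbouring genes moved together, 10880 genes were ordered along the chromosomes and taken in 423 runs of 25. The standard deviation (SD) of the run medians was divided by its mean over 1000 shuffles of the gene order. As an added alternative, the median of the 24 nearest genes was taken off each gene. Both steps were chosen after the KHOS values were seen.

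Detected probes per array ranged from 14382 to 17335, and the number of arrays limits the precision. The scripts were tested on simulated data with the array spread of these groups. In the KHOS contrast, over 5 runs with 200 changed probes among 18030, limma recovered 0.8% of changes of 0.5 on the log2 scale, 50% of changes of 1, 91.2% of changes of 2 and 100% of changes of 4. Of the calls 4.87% were false, and the T98G contrast, which held no change, gave 0 calls. In the measured KHOS data 28.8% of the probes were called. The adjusted threshold was therefore less strict there, and these recovery rates do not describe it. Among 10889 genes, camera found a list shifted by 0.5 in 20 of 20 runs of the KHOS contrast and called 1 other list over all runs. Genes were simulated as independent and with no other changes, so these runs cannot vouch for list calls among correlated genes. With 10880 genes of the KHOS contrast, the run ratio was 1.02 with no shifted run and 3.58 with 1 in 5 runs shifted by 0.5. These genes too were simulated as independent and with no other changes, so the 2 ratios set no scale for the measured ones.

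The alternatives were other background corrections, offsets and normalizations, no filter and a stricter filter on dim probes, the submitters' processed values, each line fitted alone, trended and robust variance priors, other thresholds, the mean over probes of a gene, a replicate block and leaving out each array. A test on seed matches of miR-190 in 3' untranslated regions was not run, since no such sequences were at hand. Sequences of the vectors and protein measurements were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.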

Results

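Gene expression was measured in KHOS osteosarcoma cells and T98G glioblastoma cells that carried either a GFP vector, as the control, or a miR-190 vector. Each of the 4 groups held 2 arrays. The median signal per array, on the linear scale before background correction, was 86.6 and 92 in KHOS GFP, 93.9 and 95.7 in KHOS miR-190, 140.1 and 140 in T98G GFP, and 177.3 and 160.45 in T98G miR-190. Between 30.39% and 36.64% of the 47318 probes were above background on an array, and 18030 probes were tested. Unless stated otherwise, a value below is a log2 fold change of miR-190 over GFP with its standard error (SE) from limma, with n = 2 arrays per group.

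The median SD between replicate arrays was 0.137 in KHOS GFP, 0.122 in KHOS miR-190, 0.128 in T98G GFP and 0.116 in T98G miR-190. Across probes, replicate arrays correlated at 0.980 to 0.983 in KHOS and at 0.989 to 0.991 in T98G. Arrays with different vectors correlated at 0.920 to 0.929 in KHOS and at 0.987 to 0.989 in T98G, and arrays of different lines at 0.838 to 0.867. Probes are not independent replicates, so these correlations describe the arrays and carry no test.

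The question in each line was which transcripts differ between cells that, per the labels, carry a miR-190 vector and cells that carry GFP. In KHOS cells with miR-190, transcripts of the cancer-testis families, whose normal expression is largely limited to germ cells, were mostly at background. GAGE4 was at least 156-fold lower (adjusted p = 6.27e-07), and the melanoma-associated antigen MAGEA10 was at least 33.6-fold lower. The MHC class I genes, which present peptides to T cells, were lower as a list by camera with the preset correlation and not with an estimated one (adjusted p = 0.00027; adjusted p = 0.242), and 12 of 17 tested members fell, HLA-B at -3.27 (SE 0.19, adjusted p = 9.27e-05). In the lists for the type I interferon response, inflammation and TGF-beta signalling, 13 of 32, 8 of 18 and 10 of 23 members fell, while CCND2, which encodes cyclin D2, and the sodium channel gene SCN9A rose.

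In all, limma called 5186 probes in KHOS, 2676 higher and 2510 lower with miR-190, which is 28.8% of those tested. At an unadjusted p under 0.05 there were 7526, where chance gives 902. By the probe per gene with the highest mean, 3408 of 10889 genes were called, 1677 higher and 1731 lower. Genes called by another probe alone are not in that count. The large fitted changes were mostly falls: 402 called probes fell and 57 rose by at least 2 on the log2 scale, and 164 fell and 0 rose by at least 3. These counts use the fitted values also for probes not above background in a group, whose bounds can be smaller. Probes above background on both GFP arrays and on neither miR-190 array numbered 704, and 447 showed the reverse. The labels do not say whether replicate arrays came from separate cultures, so the p-values measure the spread between arrays, which may be smaller than that between infected populations. Without KHOS miR-190 replicate 1 the count was 3080 and without KHOS GFP replicate 1 it was 3387, with the lone array assumed to vary like the other groups. The balance of directions depended on the processing: 2145 probes were higher and 3066 lower with median scaling, 2374 and 2818 with cyclic loess, 1356 and 1724 without KHOS miR-190 replicate 1, and 1582 and 1805 without KHOS GFP replicate 1.

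**Figure D1:**
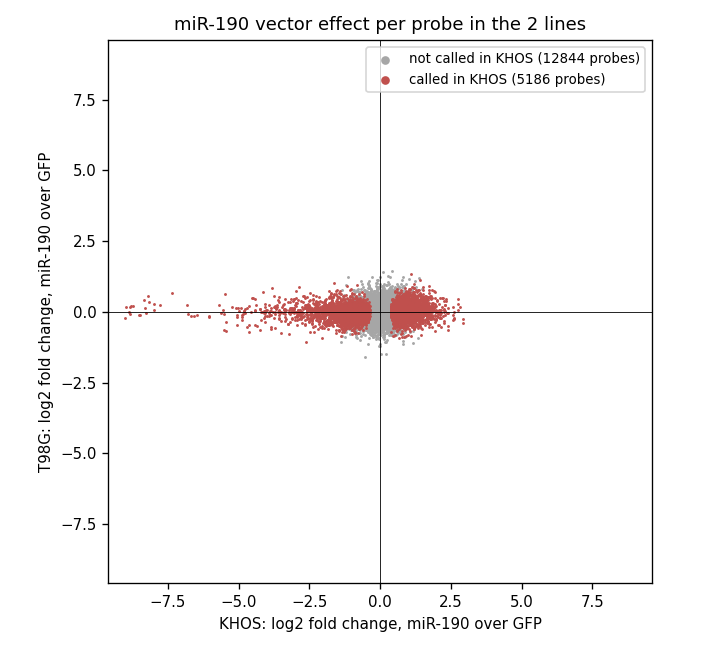
Log2 fold change of miR-190 over GFP per tested probe, KHOS on the horizontal and T98G on the vertical axis, with the 5186 probes called in KHOS in red and the other 12844 in grey. The red points spread along the KHOS axis, to -9.02 at the lowest, and no probe reached the threshold in T98G.

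Among the genes that rose in KHOS, PDE7B, a cyclic AMP phosphodiesterase, was at least 7.47-fold higher (adjusted p = 0.00144), SCN9A at least 4.74-fold (adjusted p = 0.00433) and CCND2 at least 6.68-fold (adjusted p = 0.000256). The potassium channel gene KCNK1 was at least 5.92-fold higher (adjusted p = 0.000169) and CYFIP2, which encodes a regulator of actin assembly, at least 4.68-fold (adjusted p = 0.00223). These 5 were above background on 1 of the 2 GFP arrays, so their folds are bounds too. The other 7 were above background on neither GFP array. The tetraspanin TSPAN13 was at least 3.64-fold higher, MIR155HG, the host transcript of miR-155, at least 2.79-fold, the dehydrogenase gene SDR42E1 at least 2.53-fold, the potassium channel subunit KCNG3 at least 2.39-fold, the neurotrophin BDNF at least 2.33-fold, the neuronal pentraxin NPTX1 at least 2.32-fold and the chromatin remodeller CHD5 at least 2.21-fold. For NPTX1, 1 of 3 tested probes rose, and the others were at 0.22 and 0.01.

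The 12 genes named for the largest falls in KHOS were above background on both GFP arrays and on neither miR-190 array. They were GAGE4, GAGE12C, GAGE12G, GAGE12B, GAGE12H, GAGE12J, GAGE12F, GAGE2A, GAGE12E, MAGEA10, BEX1 and TGM2. These GAGE genes were lower by at least 39.3-fold (GAGE12E) to at least 156-fold (GAGE4 and GAGE12G). They are near-identical copies, so a probe named for a member may read its relatives. BEX1, a brain-expressed gene of the X chromosome, was at least 57.8-fold lower (adjusted p = 4.61e-07), and TGM2, which encodes the protein-crosslinking enzyme transglutaminase 2, at least 51-fold lower (adjusted p = 1.68e-05). For BEX1, 1 of 2 tested probes fell, and the other was at -0.27.

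The cancer-testis families were then counted as 1 group, a grouping chosen after the KHOS values were seen. Of 42 tested probes from 29 genes, 35 fell and 0 rose in KHOS. All 12 GAGE probes fell, with bounds from 7.32-fold to 160-fold, as did all 11 MAGE probes (3.51-fold to 33.6-fold) and all 6 CT45 probes (5.52-fold to 16.7-fold). Among the SPANX genes 5 of 10 probes fell, among the CSAG genes 1 of 2, and the SSX probe did not pass. Without these families 5151 probes remained called. In T98G 14 of the 42 probes were above background on both GFP arrays, among them 0 of the 12 GAGE and 0 of the 6 CT45 probes, so most could not be seen to fall there, and 0 passed.

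**Figure D2:**
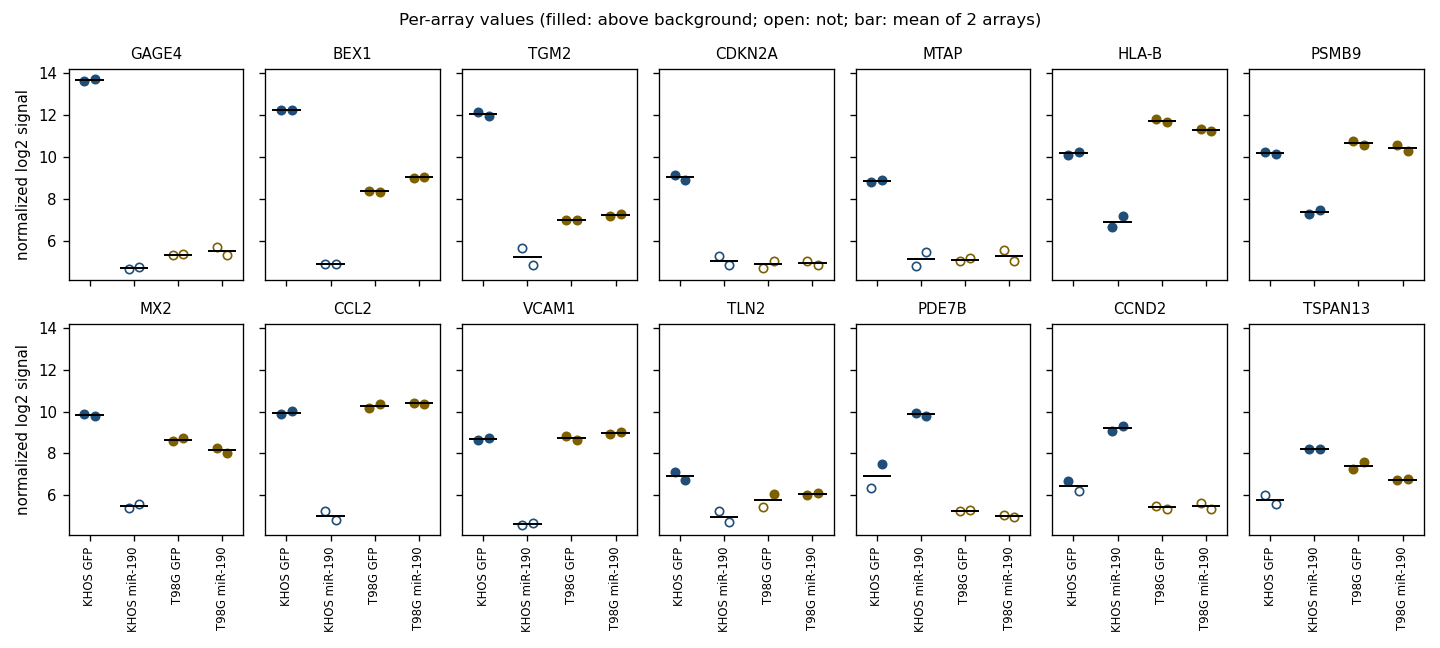
Normalized log2 signal of 14 genes on each of the 8 arrays, by line and vector, with filled points above background, open points not above background and bars at the mean of 2 arrays. In KHOS, GAGE4 fell from a mean of 13.67 to 4.70, which is background, and HLA-B from 10.17 to 6.90.

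Of the 31 gene lists tested in KHOS, 5 shifted by camera with the preset correlation, all downward, and 0 did with an estimated correlation, where the lowest adjusted p was 0.242. By fry, which tests whether members move one way and does not compare a list with other genes, 24 lists passed. In the MHC class I list, 12 of 17 tested members fell and 0 rose, with a median of -1.19 (adjusted p = 0.00027; adjusted p = 0.242 with an estimated correlation). The counts were 12 lower and 2 higher when adjusted over the list alone. Beside HLA-B, the immunoproteasome subunits PSMB9 and PSMB8 fell, at -2.80 (SE 0.15) and -1.61 (SE 0.12), as did the peptide transporter TAP1, at -1.32 (SE 0.13), and the peptide-loading factor TAPBP, at -1.35 (SE 0.16). For PSMB8, 3 of 4 tested probes fell and the other was at 0.76, and for TAPBP, 1 of 2 fell. The light chain B2M, at -0.21 (SE 0.13, adjusted p = 0.251), did not pass.

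In the type I interferon list, 13 of 32 tested members fell and 2 rose in KHOS, with a median of -0.47, or -0.37 with dim members at their bound (adjusted p = 0.00146; adjusted p = 0.242 with an estimated correlation). With p-values adjusted over the list alone, 14 fell and 3 rose. The antiviral GTPase gene MX2 was at least 11-fold lower, the virus-tethering factor BST2 at least 10.5-fold lower and OAS2 at least 2.34-fold lower, and IFIT1 fell by 2.21 on the log2 scale (SE 0.17). For OAS2, 1 of 2 tested probes fell, and the other was at -0.25. Against that direction, the RNA sensor IFIH1 was at least 1.63-fold higher. In the list of inflammatory cytokines and NF-kB targets, 8 of 18 members fell and 2 rose, also adjusted over the list alone (adjusted p = 0.0258; adjusted p = 0.336 with an estimated correlation). The monocyte attractant CCL2 was at least 11.8-fold lower, the adhesion molecule VCAM1 at least 4.96-fold, CXCL8 at least 1.93-fold and IL6 at least 1.56-fold, while the cytokine IL11 rose by 1.47 (SE 0.24). The fitted median of that list was -0.46, and -0.03 with dim members at their bound. Its call was lost with no background correction (adjusted p = 0.0518), with quantiles taken within each line (0.0544), with the submitters' values (0.0681) and without KHOS GFP replicate 1 (0.0823).

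In the TGF-beta list, 10 of 23 members fell and 3 rose in KHOS, also adjusted over the list alone, with a median of -0.54 (adjusted p = 0.00517; adjusted p = 0.336 with an estimated correlation). The ligand TGFB2 was at least 3.03-fold lower and the latent TGF-beta binding protein LTBP2 at least 4.89-fold lower, and LMCD1 and the matrix protein TGFBI fell, at -2.34 (SE 0.14) and -1.42 (SE 0.11). The inhibitor SMAD7 rose by 0.95 (SE 0.18) and CCN2 by 0.68 (SE 0.12). In the list on tumour dormancy and the balance of angiogenesis, 11 of 26 members fell and 6 rose, with a median of -0.70, or -0.64 with dim members at their bound (adjusted p = 0.0155; adjusted p = 0.268 with an estimated correlation). When adjusted over the list alone, 14 fell and 6 rose. Its falling members included genes that promote vessel growth and genes that restrain it: the angiopoietin ANGPT2 was at least 3.05-fold lower, ESM1 at least 5.63-fold, the nucleotidase NT5E at least 5.69-fold and IGFBP5 at least 3.44-fold, and the angiogenesis inhibitor THBS1 fell by 1.66 on the log2 scale. The growth factor FGF2 rose by 1.55 (SE 0.20). The call of that list was lost with the stricter filter (adjusted p = 0.0592) and without KHOS GFP replicate 1 (0.0728).

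**Figure D3:**
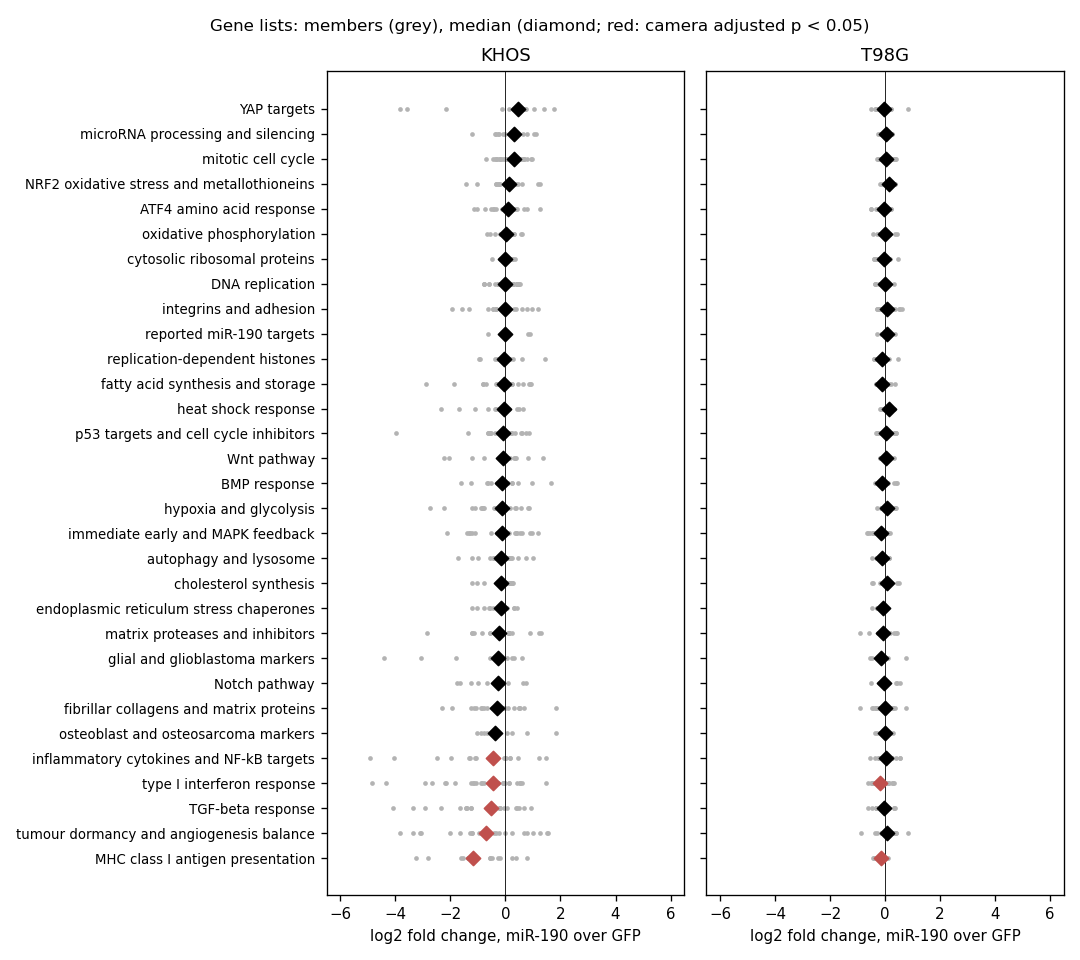
Log2 fold changes of miR-190 over GFP for the tested members of 31 gene lists (grey points) with the list medians (diamonds, red where camera with a preset correlation gave an adjusted p under 0.05), KHOS on the left and T98G on the right. The MHC class I median lay at -1.19 in KHOS and -0.16 in T98G.

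The other lists did not shift in KHOS by camera, although single members changed. For proliferation, 10 of 34 mitotic genes rose and 1 fell (adjusted p = 0.112), with the kinase gene TTK at 0.80 (SE 0.16) and the kinesin KIF20A at -0.70 (SE 0.12). Of 31 DNA replication genes 1 rose and 5 fell (adjusted p = 0.919), among them the replication clamp PCNA at -0.77 (SE 0.12). Of 22 p53 targets and cell cycle inhibitors 3 rose and 3 fell (adjusted p = 0.729), and of 12 replication-dependent histone genes 2 rose and 1 fell (adjusted p = 0.923). In microRNA processing and silencing 7 of 18 genes rose and 1 fell (adjusted p = 0.21), with DICER1, which cuts microRNA precursors, at 1.11 (SE 0.15, by 1 of 2 probes) and the helicase MOV10 at -1.22 (SE 0.19). Adjusted over the list alone, 12 mitotic genes rose and 3 fell, 1 replication gene rose and 4 fell, and 8 microRNA processing genes rose and 2 fell; the counts of the other lists of this paragraph were the same.

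In metabolism and stress, 9 of 26 hypoxia and glycolysis genes fell and 1 rose in KHOS (adjusted p = 0.0825), with NDRG1 at -2.75 (SE 0.14) and the glycolysis regulator PFKFB4 at -2.23 (SE 0.15). Of 17 cholesterol synthesis genes 3 fell and 0 rose (adjusted p = 0.285), and of 18 genes of fatty acid synthesis and storage 4 rose and 5 fell (adjusted p = 0.559), with the acetyl-CoA synthetase ACSS2 at -2.89 (SE 0.11). Of 16 endoplasmic reticulum chaperones 6 fell and 0 rose (adjusted p = 0.112), of 28 ATF4 targets 4 rose and 7 fell (adjusted p = 0.729), and of 18 heat shock genes 1 rose and 4 fell (adjusted p = 0.229), with HSPA1A at -2.36 (SE 0.21). Of 21 NRF2 targets and metallothioneins 3 rose and 2 fell (adjusted p = 0.766), of 22 autophagy and lysosome genes 2 rose and 5 fell (adjusted p = 0.21), and of 24 oxidative phosphorylation genes 1 rose and 2 fell (adjusted p = 0.84). Of 26 cytosolic ribosomal protein genes 0 changed (adjusted p = 0.995). Adjusted over the list alone, 3 hypoxia genes rose and 9 fell, 5 fatty acid genes rose and 6 fell, 1 chaperone rose and 6 fell, and 2 lysosomal genes rose and 6 fell; the counts of the other lists of this paragraph were the same.

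In matrix and signalling, 10 of 23 collagens and matrix proteins fell and 2 rose in KHOS (adjusted p = 0.108), with the laminin LAMB1 at -2.30 (SE 0.13) and the collagen COL8A1 at 1.85 (SE 0.12, with 2 of 3 probes rising). Of 19 matrix proteases and inhibitors 3 rose and 5 fell (adjusted p = 0.226), and of 21 integrin and adhesion genes 3 rose and 3 fell (adjusted p = 0.838). Of 22 immediate early and MAPK feedback genes 5 rose and 7 fell (adjusted p = 0.575), with the MAPK phosphatase DUSP6 at -1.11 (SE 0.13). Of 17 YAP targets 8 rose and 3 fell (adjusted p = 0.183), with a median of 0.44 and a mean of -0.03: ANKRD1 was at least 3.53-fold lower. Of 15 Wnt pathway genes 3 rose and 3 fell (adjusted p = 0.729), with the secreted inhibitors SFRP1 and DKK3 at -2.24 (SE 0.15) and -2.04 (SE 0.13); 2 of 3 DKK3 probes fell. Of 12 Notch pathway genes 2 rose and 4 fell (adjusted p = 0.112), and of 15 BMP response genes 2 rose and 5 fell (adjusted p = 0.521). Adjusted over the list alone, 3 proteases and inhibitors rose and 6 fell, 4 adhesion genes rose and 4 fell, 6 immediate early genes rose and 7 fell, 10 YAP targets rose and 3 fell, 3 Wnt genes rose and 4 fell, and 2 Notch genes rose and 5 fell; the counts of the other lists of this paragraph were the same.

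Among markers of cell types, 4 of 9 tested osteoblast and osteosarcoma genes fell in KHOS and 1 rose (adjusted p = 0.65), with the osteoblast regulator RUNX2 at -1.03 (SE 0.21) and the bone alkaline phosphatase ALPL at least 1.95-fold higher; adjusted over the list alone, 4 fell and 2 rose. Of 8 glial and glioblastoma genes 3 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.15): SLC1A3 was at least 6.27-fold and NES at least 5.85-fold lower, and SOX9 fell by 1.80 on the log2 scale (SE 0.22). Fewer than 5 genes were tested in the remaining marker lists. Of 4 blood cell markers CD14 fell, by at least 5.19-fold (adjusted p = 0.000306; above background on 1 of 2 miR-190 arrays), of 3 epithelial markers EPCAM rose, at 1.67 (SE 0.15), and KRT8 fell, at -0.47 (SE 0.11), while the KRT18 probe with the highest mean was at -0.35 and the other rose, of 2 endothelial markers 0 passed, and of the pluripotent and germ cell markers 0 of 7 could be tested.

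Beside these gene groups, neighbouring genes on a chromosome shifted together in KHOS. The medians of runs of 25 neighbouring genes had an SD of 0.277 against 0.129 in shuffled order, a ratio of 2.14 (permutation p = 0.001, the smallest that 1000 shuffles can give). Between replicate arrays the permutation p was 0.001 to 0.002 too, so the p alone does not set the vectors apart. The ratio was 1.13 to 1.39 between replicate arrays, 1.54 for the vectors in T98G and 1.96 for KHOS GFP against T98G GFP. Of 423 runs, 25 had a KHOS median below -0.4 and 35 above 0.4, while 0 runs lay beyond 0.4 in T98G or between the KHOS GFP replicates. The lowest run, from ZNF655 to POP7, had a median of -0.91 with 23 of 25 genes below 0, and the highest, from KIAA0408 to MAP3K5, a median of 0.79 with 1 gene below 0.

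**Figure D4:**
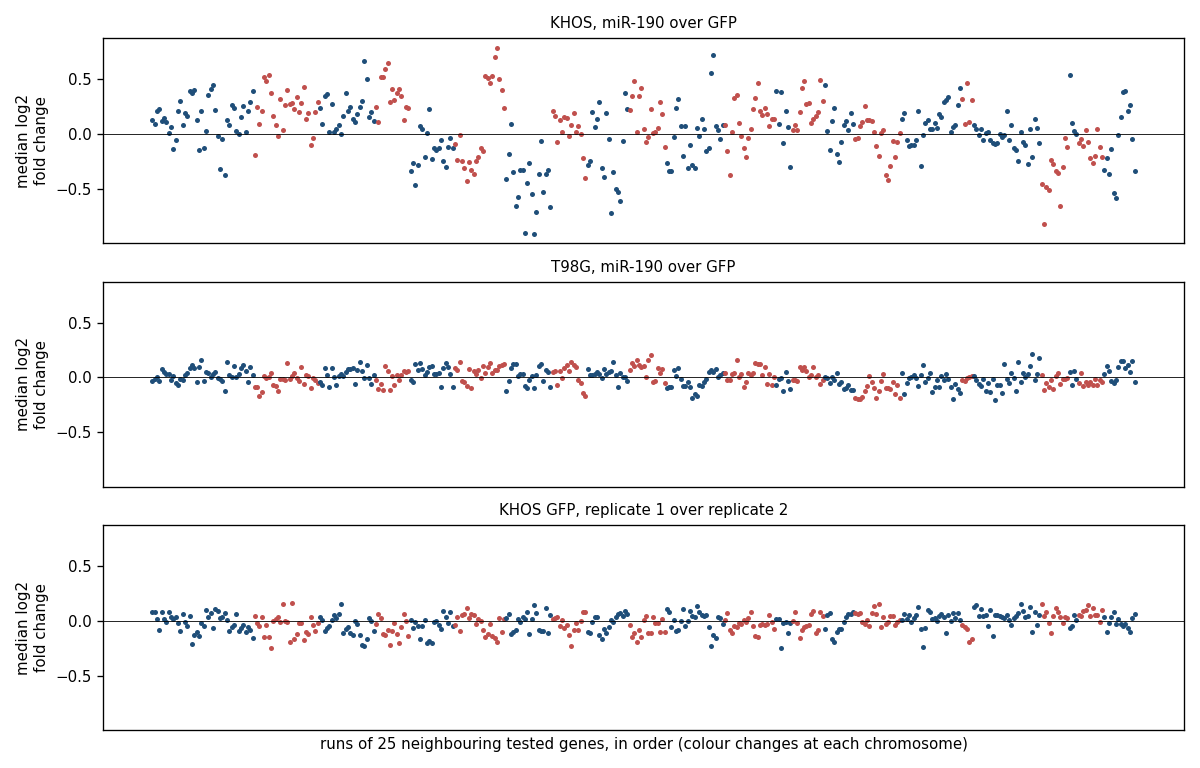
Median log2 fold change of each of 423 runs of 25 neighbouring tested genes in chromosome order, for miR-190 over GFP in KHOS (top) and T98G (middle) and for KHOS GFP replicate 1 over replicate 2 (bottom). In KHOS 60 runs lay beyond 0.4 in either direction, in the other panels 0.

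Several genes of KHOS GFP cells were not above background in KHOS miR-190 cells, a selection made after the values were seen. The neighbouring genes MTAP and CDKN2A, which encode a purine salvage enzyme and the cell cycle inhibitor p16, were at least 5.48-fold (adjusted p = 0.000195) and at least 6.19-fold lower (adjusted p = 6.87e-05; at least 5.02-fold by another probe), and CDKN2B, which encodes the related inhibitor p15, was at least 4.1-fold and at least 7.83-fold lower by 2 probes. The glutathione transferase GSTT2B was at least 2.83-fold and at least 2.38-fold lower by 2 probes. NDUFB4 was at least 19.4-fold lower by its tested probe (adjusted p = 2.11e-06). An untested NDUFB4 probe went the other way, above background on 1 KHOS miR-190 array and on no KHOS GFP array. Another untested NDUFB4 probe was above background on no array, so the fall rests on the tested probe alone. CDKN2A, CDKN2B and GSTT2B each also had 1 untested probe, which was above background on no array. In T98G, MTAP, CDKN2A, GSTT2B and the tested NDUFB4 probe were not above background with either vector, and CDKN2B was above background with both.

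In T98G cells with miR-190, the interferon and antigen presentation lists shifted slightly down relative to the other genes, by camera with the preset correlation. No gene passed on its own. In the MHC class I list, 16 of 17 members lay below 0, with a median of -0.16 (adjusted p = 0.00553; adjusted p = 0.485 with an estimated correlation). HLA-B was at -0.44 (SE 0.19, adjusted p = 0.695) and PSMB9 at -0.22 (SE 0.15, adjusted p = 0.814). In the type I interferon list, 23 of 32 members lay below 0, with a median of -0.18 (adjusted p = 0.0374; adjusted p = 0.526 with an estimated correlation), and MX2 was at -0.52 (SE 0.14, adjusted p = 0.646). In both lists 0 members passed adjusted over the list alone. By fry, which tests against no change, the MHC class I list alone passed (adjusted p = 0.0165), and the interferon list did not (adjusted p = 0.147).

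By limma, 0 of 18030 probes were called in T98G, with 1295 at an unadjusted p under 0.05, where chance gives 902, and a smallest adjusted p of 0.327. The fitted fold changes had an SD of 0.261, against 0.822 in KHOS, and 41 probes lay beyond 1 on the log2 scale. That count also takes probes not above background in a group at their fitted values, whose bounds can be smaller. Among the rising genes with the smallest unadjusted p, all of which miss the threshold, were the secretory granule protein SCG5 at 1.23 (SE 0.13, adjusted p = 0.327), the surface glycoprotein CD24 at 0.90, PSG7 at 0.94, the ubiquitin ligase subunit SKP2, above background on 1 GFP array, at 0.87 or more, KLHDC10 at 0.75 and GLT1D1, above background on neither GFP array. Among the falling ones were the MHC class II invariant chain CD74 at -1.60 (SE 0.20, adjusted p = 0.327), the BMP antagonist SOSTDC1 at -1.12, the junction molecule JAM3 at -0.70, and FBN2, GUCY1A1 and LINC03122, above background on neither miR-190 array. Adjusted over the list alone, 1 of 23 collagens and matrix proteins rose, COL8A1 at 0.76 (SE 0.12), and 1 fell, FBN2; in the other T98G lists 0 members passed. The T98G lists that did not shift had an adjusted p of 0.0632 or more; among them the median and the mean differed in sign for DNA replication, collagens and matrix proteins, the Notch pathway, oxidative phosphorylation and the osteoblast markers. The interferon list was lost without T98G GFP replicate 1 (adjusted p = 0.0855), T98G GFP replicate 2 (0.113) or T98G miR-190 replicate 1 (0.167), and with median scaling (0.0887), no filter (0.0921), the mean over probes (0.0874) or fry (0.147). With the submitters' values limma called 47 T98G probes, 30 higher and 17 lower.

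The design also asks whether miR-190 acts alike in both lines. The interaction term compares how the miR-190 and GFP populations differ in each line. It cannot tell miR-190 from other differences between the infected populations. GDF15, TSPAN13 and KCNK1, which rose in KHOS, were above background in T98G, and by that term their change differed between the lines. The interaction term also passed for GAGE4 and 4 other GAGE genes and for PDE7B and SCN9A, but these were not above background in T98G with either vector, so that a fall of the GAGE genes could not be measured there and their term restates the KHOS fall. The interaction term passed for 2095 probes, with 1253 effects higher and 842 lower in T98G than in KHOS, and 5155 at an unadjusted p under 0.05. GDF15, a stress-induced cytokine, rose by 2.39 in KHOS (SE 0.21) and was at -0.52 in T98G (SE 0.21, adjusted p = 0.694). Of the 31 lists, 6 differed by camera with the preset correlation, among them MHC class I antigen presentation (adjusted p = 0.00343) and the inflammatory list (adjusted p = 0.01), and 0 with an estimated one, where the lowest adjusted p was 0.356; fry passed 16. The count of 2095 fell to 1392 without KHOS miR-190 replicate 1, to 925 and 1062 without T98G GFP replicates 1 and 2, and to 881 and 897 without T98G miR-190 replicates 1 and 2.

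With line and vector as additive terms, limma called 0 probes for a common effect, with 3809 at an unadjusted p under 0.05, where chance gives 902, and a smallest adjusted p of 0.196. In that fit the difference between the lines adds to the residual spread, so the count of 0 does not show that shared changes were absent. Nor do the 3809 show that they were present, since the fitted effect averages both lines and changes in KHOS alone can raise it. With 0 calls in T98G, no overlap of called genes could be counted. Across 10889 genes, which are not independent replicates, the fold changes of the lines correlated at 0.102 (Pearson) and 0.135 (Spearman). Of the 3408 genes called in KHOS, 1961 (57.5%) had the same sign in T98G.

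The microRNA itself was not measured by these arrays. The precursor probes for MIR190A and MIR190B were above background on 0 of the 8 arrays. TLN2, the talin gene that holds the MIR190A locus, was at least 1.44-fold lower with miR-190 in KHOS (adjusted p = 0.00371) and did not pass in T98G (adjusted p = 0.864), where 1 GFP array was not above background. Of 7 reported targets of miR-190, 5 were tested in KHOS, and 0 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.766, with a median of -0.02 and a mean of 0.19). The RNA-binding protein QKI rose by 0.88 on 1 of its 3 tested probes (SE 0.23, adjusted p = 0.0307), a call lost with median scaling (adjusted p = 0.129) and without KHOS GFP replicate 1 (adjusted p = 0.121), among others. The TGF-beta mediator SMAD2 was at 0.82 (SE 0.31, adjusted p = 0.0904). TP53INP1, above background on 1 GFP and 0 miR-190 arrays, did not pass (adjusted p = 0.185), and the phosphatase PHLPP1 was at -0.11 (SE 0.23, adjusted p = 0.77). VHL was at -0.02 (SE 0.13, adjusted p = 0.935) by the probe with the highest mean. Its other tested probes were at 0.82 (SE 0.38, adjusted p = 0.157) and 0.38 (SE 0.17, adjusted p = 0.134) and did not pass either. In T98G 0 of the 5 passed (camera adjusted p = 0.952).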

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

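Of the tests below, the ratio of neighbouring runs and the search for T98G transcripts in KHOS cells were chosen only after the KHOS result was seen, and taking off the neighbours' median, testing the MHC class I list without HLA genes and setting list members to their bound were added after seeing the data.

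Results are listed here because the change from GFP to miR-190 cells differed between the lines by the interaction test. That test passed for 2095 probes, and for 881 to 1802 when any 1 of the 8 arrays was left out. The differences of the fitted log2 effects, T98G minus KHOS, were 9.14 for GAGE4, 9.01 for GAGE12G, 8.86 for GAGE12C, 8.45 for GAGE12J and 8.39 for GAGE12B, probes that were not above background in T98G, so that these fitted values depend on the background offset and are no bounds. They were -3.32 for SCN9A and -3.20 for PDE7B, also not above background in T98G, -3.07 for TSPAN13, -2.91 for GDF15 and -2.87 for KCNK1. TSPAN13 was above background on neither KHOS GFP array, and SCN9A, PDE7B and KCNK1 on 1 of 2, so these values also depend on the offset. Among the gene lists, the median differences were 0.20 for the type I interferon response, 0.793 for MHC class I antigen presentation, 0.543 for inflammatory cytokines and NF-kB targets, 0.381 for the TGF-beta response, 0.586 for tumour dormancy and angiogenesis and 0.196 for hypoxia and glycolysis. With members not above background at their bound, they were 0.14 for the interferon, 0.392 for the inflammatory and 0.491 for the dormancy list, and the KHOS median of the inflammatory list was -0.03 in place of -0.46. The adjusted p by camera ran from 0.00343 to 0.0344 over these 6 lists, and 0 passed with an estimated correlation.

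In KHOS 5186 probes differed between the miR-190 and GFP populations. T98G cells swapped with or mixed into the miR-190 cultures were argued against, since 3 of the 50 brightest probes found in T98G GFP and not in KHOS GFP were above background on both KHOS miR-190 arrays. A difference in genome copy number between the KHOS populations may account for part of the pattern. The medians of neighbouring runs spread 2.14 times as widely as in shuffled order, against 1.39 at most between replicates. The ratio also lay above that of replicates for the vectors in T98G (1.54) and for KHOS GFP against T98G GFP (1.96). It therefore cannot tell a copy number change within a line from another origin of a KHOS population. The most extreme KHOS runs also differed slightly between the KHOS GFP replicates. In the highest runs, at 0.648 to 0.789, replicate 1 over replicate 2 was at -0.225 to -0.087. In the lowest, at -0.911 to -0.706, it was at 0.0107 to 0.14. A difference that also sets replicate arrays apart may therefore add to the runs, which was not tested. Once the median of the 24 nearest genes was taken off, 65.7% of the called genes stayed called, with 2939 genes called in place of 3404. This argues against shifts shared by neighbouring genes as the whole account. Copy number changes of single genes or small groups are not taken off by that step, so it cannot decide on copy number as the whole account. The effect of miR-190 itself, the selection of a subpopulation during infection and another origin of either KHOS population stay open, since each vector had 1 group per line and these were not tested apart.

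In T98G limma called 0 probes, with 1295 at an unadjusted p under 0.05. Whether a T98G array carries the wrong vector label could not be decided. The labelled split of the 4 arrays gave 1705 probes at an unadjusted p under 0.05 in a fit of that line alone. The other splits gave 750 at most, with 0 called in each. But the labelled split also parted the arrays by position on the chip and by median signal, so it could give the most probes whatever the labels. Equal splits also do not cover a single wrong label or an exchange of all labels. With 3 splits no share under 0.05 can be had. Changes that are present but too small to call with so few arrays stay open and may be part of the pattern. The fold changes of the labelled split spread 1.17 times as widely as the wider of the other splits, which position on the chip could also give. Whether miR-190 itself had a weaker effect in T98G was not tested apart from the amount of microRNA, which was not measured.

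The MHC class I list was lower in both lines by camera with the preset correlation, and in neither with an estimated one. A single deciding T98G array was argued against, since the median of the list stayed at -0.176 or lower without each of the 4 arrays. Cross-hybridization between near-identical HLA genes was argued against, since the 12 members that are not HLA genes had a T98G median of -0.155 (camera adjusted p = 0.0412; adjusted p = 0.526 with an estimated correlation), with 11 of them below 0. A lower expression of antigen presentation genes with miR-190 in both lines may therefore be proposed as a hypothesis, found and tested on the same data, and differences between the infected populations other than miR-190 stay open.

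For the common effect, limma called 0 probes, and 34 of the 34 usable splits of the 8 arrays gave at least as many, with 0 at most in the other splits, which had to be so with a count of 0, so the splits say nothing about chance.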

How the results depend on the processing

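The alternatives that take off the neighbours' median, leave out the cancer-testis families or count the cancer-testis probes were chosen after seeing the data, as was the lowest count over normalizations. No called list, and no called gene taken by the rule for named genes, changed direction under an alternative. Genes named outside that rule, such as MTAP, CDKN2B, GSTT2B and NDUFB4, were not followed over the alternatives. The balance of the KHOS calls did change direction: 2676 were higher and 2510 lower, against 2374 and 2818 with cyclic loess, 2145 and 3066 with median scaling, 1662 and 1943 with no filter, 1786 and 1939 with the replicate block, 1190 and 1493 with each line alone, 903 and 1276 with the fold threshold, and more lower than higher without KHOS GFP replicate 1 or either KHOS miR-190 array. The count of KHOS probes, 5186, was 2179 when an absolute log2 change of at least 1 was also asked for, which by construction removes small changes, and 2683 with each line fitted alone, which leaves fewer arrays to estimate the spread. It was 3080 to 4550 with an array left out, and 2179 to 7028 over the other alternatives. Background correction and normalization did not account for the count, since the lowest over their alternatives was 5101. With median scaling the median of all tested probes in KHOS was -0.06 in place of 0.06. With a replicate block the count of KHOS probes was 3725. The replicate numbers showed no pairing of the arrays. Across probes, replicate 1 minus replicate 2 with GFP correlated with the same difference with miR-190 at -0.022 in KHOS and -0.035 in T98G. Among cancer-testis probes 35 fell under each normalization and 8 with the stricter filter, which drops most of them and under which 1 rose.

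The T98G count of 0 became 4 with cyclic loess, 3 with a trended prior, 9 with median scaling, 3 with no background correction, 9 with quantiles within each line and 47 with the submitters' values; it was 0 to 0 with an array left out. The interaction count was 3477 at an adjusted p under 0.1, 1069 with no filter, 962 with the replicate block and 881 to 1802 with an array left out. The common effect gave 9 probes with the submitters' values. Genes called the same way in both lines numbered 1 with a trended prior, 1 with median scaling and 5 with the submitters' values. The cause of these shifts was not tested. The KHOS gene lists numbered 0 with an estimated correlation, 24 with fry, which does not compare a list with other genes, and 3 to 5 with an array left out, 3 being without KHOS GFP replicate 1. The T98G lists numbered 5 at an adjusted p under 0.1, 0 with an estimated correlation, 4 with cyclic loess, 4 with a trended prior, 1 with fry, 4 with median scaling, 4 with no background correction, 1 with no filter and 1 to 3 with an array left out. The correlation between the lines stayed between 0.0723 and 0.123. Of the values of named genes in KHOS under the alternatives, 3261 kept direction and side of the threshold, 134 lost their call, 18 gained a call and 8 that were uncalled changed sign. In T98G these were 3201, 0, 30 and 88, for the lists 1305, 20, 50 and 50, and for the interaction genes 199, 4, 0 and 0. A robust prior and the threshold on fold change were not run for the lists. Signal over background limits the dim probes, which carry bounds in place of folds.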

Other observations

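Of the tests below, that of the vector's microRNA, that of lost neighbours and the lists on neighbour-corrected values were chosen only after the results were seen.

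Of 8847 genes above background on both KHOS GFP arrays, 400 were above background on neither KHOS miR-190 array. Among them 31 pairs of neighbouring genes with unlike names were both lost, against a mean of 17.2 and a highest of 34 in 1000 shuffles of the gene order (permutation p = 0.003). MTAP and CDKN2A were such a pair, as were GPC2, a glypican gene, and STAG3, which encodes a meiotic cohesin subunit. Pairs of cancer-testis genes whose names begin unlike, such as SPANXD with MAGEC2 and MAGEA12 with CSAG3, were counted too. The excess over shuffled order is therefore not free of related genes. Of the 50 brightest probes found in KHOS GFP and not in T98G GFP, 27 were above background on both KHOS miR-190 arrays.

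After the median of the 24 nearest genes was taken off, 7 gene lists passed by camera in KHOS in place of 5, with an adjusted p of 0.00132 for MHC class I antigen presentation and 0.000878 for the type I interferon response. With an estimated correlation 0 passed, and the lowest adjusted p was 0.228.

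Expression of the vector's microRNA was looked for in the precursor probes. Of their readings on the miR-190 arrays 0 were above background, which decides nothing, since the probes do not read the mature microRNA.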
